A study of Mus musculus with 6 samples.

How the data were processed

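The series holds 6 samples of C2C12 myoblasts: 3 RNA-seq libraries (siNS non-starved, siNS starved for 4 h, siFoxk1 non-starved), ChIP-seq of Foxk1 and of Sin3A in non-starved cells, and a ChIP input. Each group has 1 sample, and the groups were taken from the sample titles. A file of the input sample is not analysed here.

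Per the file headers, the authors gave RNA values as mean FPKM with the lower and upper limits of a 95% interval. The submitters' processing notes list TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks 2.1.1, Cuffdiff and build mm9, without roles or options. How the intervals were computed, which annotation was used, and whether the word mean stands for pooled replicates are not given in the sources used here. The deposited FPKM values were used without rescaling. FPKM keeps no read counts, and low values showed no whole-read steps, so the depth is unknown and no count model was run. For ChIP-seq the submitters' processing notes list BWA 0.7.5a, SAMtools 0.1.19, bedtools and build mm9. The deposited lists give the chromosome and the left and right boundary of each region, with no score, and the caller, its thresholds and any merging of samples are not given in the sources used here.

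In the RNA files, 364 rows combined several gene symbols, 388 rows belonged to 161 symbols with several rows, and 679 rows were short RNAs by name. The mean exceeded its own upper limit in 353, 340 and 289 rows of the control, starved and knockdown tables. The row of Zzz3 was left out because its limits were in the wrong order in the knockdown table, leaving 22988 rows.

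Fold changes were log2((FPKM + 1)/(FPKM of the control + 1)), which understates the change of low genes, while ratios given as times are of the plain FPKM. A row entered a comparison at 1 FPKM or more in at least 1 of its 2 libraries and was counted at 2-fold or more. With 1 library per group no test, p-value or standard deviation can be given. The median fold change of all rows was -0.01 in the starved and 0.02 in the knockdown comparison, so the fold changes need no centring.

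The 25 gene lists, written before the data were examined, covered starvation programs (autophagy core, muscle atrophy, proteasome, lysosome, amino acid response, FoxO targets), growth (serum immediate early, cholesterol synthesis, cell cycle, ribosomal proteins, ribosome biogenesis), identity and complexes (myogenic differentiation, extracellular matrix, Foxk and Sin3 complex), stress (p53 targets, interferon response, hypoxia and glycolysis, ER stress, heat shock, NRF2 targets, polyA quality) and 4 marker lists of other cell types. Of 853 listed genes, 824 were found as single rows. Matching through RefSeq synonyms (assembly GRCm38.p6) placed 5 members under older symbols, and 18 genes stood in more than 1 list. The median of each list with at least 5 expressed members was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list stands apart outside the central 95%. This describes the libraries and tests nothing about the conditions.

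Genes are named by a rule written before the data were examined: 21 fixed genes, the 10 highest and 10 lowest of each comparison among rows at 5 FPKM or more in at least 1 library (leaving out names of short RNAs), the 10 largest changes shared in each direction, and up to 4 members of each list with the largest changes. Genes counted in opposite directions, members apart in both comparisons, and regions named by width were chosen after their values were seen. The rule also asked for the highest-scoring regions and regions near listed genes, which could not be named without a score or an annotation of mm9.

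Unchanged libraries sharing 1 control were simulated 1000 times with the relative width of the authors' intervals. Regions were overlapped with a minimum of 1 shared base after 6 repeated Sin3A lines were removed, exact Clopper-Pearson intervals were computed for shares, and regions were placed at random 100 times within their chromosomes. Coordinates are given from base 1. Comparisons planned between regions and transcription start sites or gene expression were not run.

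The scripts were tested on simulated data. A simulated comparison of the starved with the control library used 8356 single-gene rows without short RNAs, at 5 FPKM or more in the control. Both libraries were given the interval widths of the control. Genes changed 2.5-fold upward were called in 92% of cases, 4-fold upward in 100%, 2.5-fold downward (a ratio of 0.4) in 82% and 4-fold downward (0.25) in 100%. Of unchanged genes, 0.123% were called. Rows under 5 FPKM, short RNAs and combined rows, which the counts below include, were not covered. Of 200 simulated unshifted lists, whose genes were independent of one another, 5.5% fell outside the central 95%. Alternatives covered the pseudocount, the filter, the scaling, the fold threshold, the list statistic and the overlap rule. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and overlaps were checked with bedtools 2.31.1.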

Results

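RNA sequencing and chromatin immunoprecipitation sequencing (ChIP-seq) were performed in C2C12 cells, a mouse myoblast line with the strain label C3H. Polyadenylated RNA was profiled in 3 libraries: non-starved myoblasts given the siRNA called siNS (the control library), siNS myoblasts starved for 4 h in Hank's balanced salt solution (the starved library), and non-starved myoblasts given siRNA against Foxk1 (the Foxk1 knockdown library). ChIP-seq gave 1 list of genomic regions for Foxk1, a forkhead transcription factor, and 1 for Sin3A, the scaffold of a histone deacetylase complex, both in non-starved myoblasts. The stated purpose was to map both proteins on chromatin and to profile expression after starvation or Foxk1 depletion.

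Each RNA library listed 22989 rows of gene symbols with a mean FPKM and a 95% interval. FPKM summed to 566814 in the control, 527687 in the starved and 562507 in the knockdown library, and 11101, 11172 and 11139 rows reached 1 FPKM. Read depth is unknown. Among rows at 5 FPKM or more the median half-width of the interval was 18.1% of the value in the control, 20.1% in the starved and 19.9% in the knockdown library. Each group had 1 library, so no spread between replicates could be measured, no gene was tested, and no difference between libraries has a replicate check. A gene is called apart between 2 libraries where the authors' intervals do not overlap, which compares these libraries and not the conditions. Without regard to size, 1390 of 11396 expressed rows were higher apart and 1246 lower apart in the starved library. In the knockdown library 1010 of 11357 were higher apart and 810 lower apart. Counts of list members apart are to be read beside these shares, and counts near them set no list apart.

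Foxk1, the target of the siRNA, stood at 9.09 FPKM (95% interval 7.76 to 10.4) in the control library and at 5.15 FPKM (4.29 to 6.02) in the knockdown library, a ratio of 0.567 with the intervals apart. In the starved library it stood at 16.1 FPKM (13.3 to 18.9), 1.77 times the control. Its paralog Foxk2 was at 33.7, 25.3 and 29.9 FPKM in the control, starved and knockdown libraries, with overlapping intervals in both comparisons. Sin3a was at 19 FPKM (16.2 to 21.8) in the control and 28.7 FPKM (24.2 to 33.2) in the starved library, and at 19.9 FPKM in the knockdown library. Sin3b was at 84.3, 74.8 and 88.4 FPKM, with overlapping intervals.

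**Figure D1:**
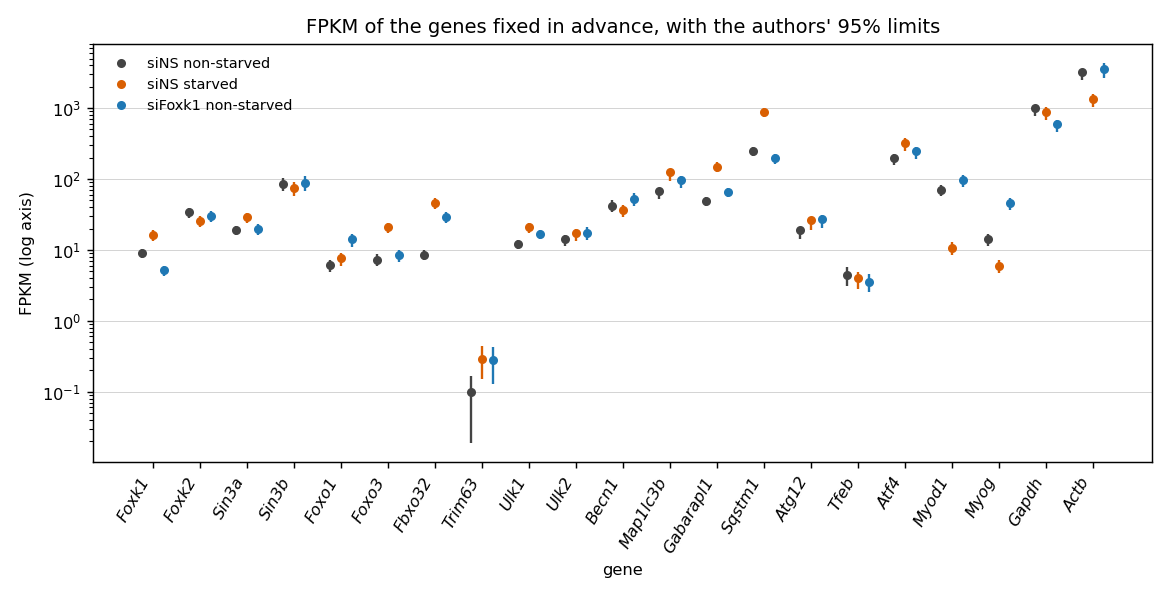
FPKM (log axis) of the 21 genes fixed before the data were examined, in the control (grey), starved (orange) and Foxk1 knockdown (blue) libraries. Points are the deposited means and lines the authors' 95% limits; Fbxo32 stands at 8.59, 45.8 and 29.0 FPKM in the 3 libraries and Myog at 14.2, 6.02 and 45.4 FPKM.

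The first comparison asked which transcripts differed after starvation, with the starved library set against the non-starved siNS library. Among the highest genes were those of the amino acid response, which ATF4 and CHOP activate when amino acids run short. Of 46 expressed members, 33 were higher with intervals apart and 0 were lower, and the list median was a log2 fold change of 0.80. Trib3, a stress-induced pseudokinase, was at 3.53 FPKM (2.74 to 4.31) in the control and 82.7 FPKM (67.2 to 97.4) in the starved library, a ratio of 23.4. Ddit3, which encodes CHOP, went from 23.4 FPKM in the control to 266 FPKM in the starved library, and the lipoprotein receptor gene Vldlr from 0.561 to 9.24 FPKM. Atf4 itself was at 200.3 FPKM (159 to 228) and 318 FPKM (249 to 373).

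Genes known as FoxO targets had the highest list median of the starvation comparison, 1.03, where the central 95% of random lists matched on expression lay between -0.21 and 0.15. Of 31 expressed members, 21 were higher apart and 4 were lower apart. The log2 fold changes were 3.10 for Gadd45a, 2.72 for Txnip and 2.29 for Fbxo32, which encodes the muscle ubiquitin ligase atrogin-1, while Errfi1 was lower at -2.76. In the overlapping list of muscle atrophy genes the median was 0.47, with 15 of 30 members higher apart and 3 lower apart. Trim63, which encodes the ubiquitin ligase MuRF1, was under 1 FPKM in all 3 libraries. Foxo3 was at 7.31 FPKM in the control and 20.7 FPKM in the starved library, with intervals apart, and Foxo1 at 6.08 and 7.78 FPKM, with intervals overlapping.

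Autophagy and lysosome genes were also higher in the starved library. In the autophagy core list 14 of 47 expressed members were higher apart and 0 lower apart (median 0.32). The p62 receptor gene Sqstm1 was at 246 FPKM (209.9 to 283) in the control and 878 FPKM (738 to 1018) in the starved library, and the ATG8 family gene Gabarapl1 at 48.3 FPKM (41.2 to 55.5) and 149 FPKM (126 to 172). Map1lc3b, which encodes LC3B, was 1.84 times and the initiating kinase gene Ulk1 1.73 times the control, both apart, whereas the intervals of Becn1, Atg12, Ulk2 and Tfeb overlapped. In the lysosome list 19 of 51 members were higher apart and 0 lower apart (median 0.40), led by Fnip1 (log2 fold change 1.95), Flcn, which encodes folliculin, and Fnip2 (1.17); Fnip1 and Fnip2 encode partners of folliculin. The p53 target list had a median of 0.35, with 9 of 27 members higher apart, among them Eda2r (1.96) and the apoptosis gene Bbc3 (1.31), and 3 lower apart. Bbc3 also stands in the FoxO target list. The higher members Trp53inp1 (1.79) and Sesn2 (1.15) also stand in the autophagy core and amino acid response lists.

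Genes of the serum response were among the lowest in the starved library. Of 46 expressed immediate early and delayed serum response genes, 31 were lower apart and 3 higher apart, with a list median of -1.01. The matricellular genes Ctgf (log2 fold change -3.89) and Cyr61 (-3.63) and the ERK phosphatase gene Dusp6 (-3.28) led this list. Ctgf was at 154 FPKM (124 to 177) in the control and 9.46 FPKM (7.33 to 11.3) in the starved library. Outside the list, the inhibitors of bHLH factors Id3, Id1 and Id2 were lower by log2 fold changes of -4.26, -3.59 and -3.16, and the semaphorin gene Sema7a by -3.78. The extracellular matrix list, which also holds cytoskeletal genes such as Acta2, had a median of -0.50. Of its 34 expressed members, 18 were lower apart, among them Acta2 (-1.59), and 2 higher apart. Of 4 expressed markers of bone and cartilage cells, 3 were lower apart in the same library: Dmp1 (-1.83), Sox9 (-1.16) and Spp1 (-0.90).

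Ribosome assembly and sterol genes were lower as well. In the ribosome biogenesis list 25 of 40 members were lower apart and 0 higher apart (median -0.69), including Grwd1 (-1.44) and Nolc1 (-1.31). Of 73 ribosomal protein genes, many of which have pseudogene copies, none was apart in either comparison; the starved median of -0.02 lay above the central 95% of matched random lists, whose range was itself below 0 (-0.27 to -0.10). Cholesterol synthesis genes had a median of -0.35, with 7 of 26 lower apart and 1 higher apart. Of the myogenic genes, 4 of 34 were lower apart and 3 higher apart, and the list median of -0.10 was inside the random range. Myod1, the myoblast determination factor, was at 70.1 FPKM (57.6 to 82.3) in the control and 10.7 FPKM (8.49 to 12.8) in the starved library, and Myog at 14.2 and 6.02 FPKM. Actb, often used as a reference, was at 3186 FPKM in the control and 1355 FPKM in the starved library, with intervals apart.

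The medians of 3 further lists also lay below the random range in the starved library. Proteasome genes had a median of -0.32, with 6 of 33 members lower apart and 0 higher apart, and heat shock genes -0.37, with 7 of 18 lower apart and 1 higher apart. Their means lay at the 3.41 and 6.64 percentiles, inside the central 95%. ER stress genes had a median of -0.33, yet their mean of -0.05 lay at the 63.1 percentile, with Crebrf (2.53) and Herpud1 (2.04) high and 7 of 26 members lower apart. Cell cycle genes (median -0.20, 9 of 48 lower apart and 3 higher apart) lay at the 3.55 percentile, inside the central 95%, but outside it at 2.12 with a pseudocount of 5 and at 0.670 among random lists not matched on expression.

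In total, 356 of 11396 expressed rows were at least 2-fold higher and 342 at least 2-fold lower in the starved library, on the log2(FPKM + 1) scale. Of these, 320 and 267 also had intervals apart. In simulated unchanged libraries with noise as wide as the intervals, an average of 43.4 rows were 2-fold higher and 46.3 lower. With a pseudocount of 0.1 the number of higher rows was 562, and with a pseudocount of 5 the numbers were 154 and 179. Of 21 ranked lists, 7 lay above and 7 below the central 95% of random lists. By construction 5% of lists drawn gene by gene would lie outside. Members of 1 list may move together and 18 genes stood in more than 1 list, so 5% is not a chance rate for these lists. Of the rows ranked for naming, A330023F24Rik,Mir29b-2,Mir29c had the largest log2 fold change in the starved library (4.82), and the combined rows Actr5,Mir3474 and Dgcr8,Mir1306 were among the lowest (-5.02 and -4.08), all 3 with overlapping intervals.

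The second comparison asked what differed after depletion of Foxk1, with the knockdown library set against the same control. Muscle and matrix genes were higher. Of 37 expressed genes of myogenic differentiation, 22 were higher apart and 0 lower apart, with a list median of 0.74. Of the 37, 34 were also expressed in the starved comparison. The rest were under 1 FPKM in the control, entered only through the knockdown library and so had to be higher. Among rows of 5 FPKM or more the list lay at the 100 percentile. The skeletal actin gene Acta1 was at 6.59 FPKM (4.99 to 8.21) in the control and 39.0 FPKM (30.2 to 48.0) in the knockdown library, and the log2 fold changes of Tnnt1, Myl1 and Mylpf, components of the sarcomere, were 2.11, 2.05 and 1.94. Myog, which encodes myogenin, was at 14.2 FPKM (11.3 to 16.8) and 45.4 FPKM (36.0 to 53.9), 3.20 times the control, while the intervals of Myod1 overlapped.

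The extracellular matrix list had a median of 0.76, with 23 of 34 members higher apart and 4 lower apart. Tagln (2.01) and Acta2 (1.98), which encode cytoskeletal and not matrix proteins, and the collagen gene Col12a1 (1.91) were the highest of the list. Among markers of other cell types, the bone marker Dmp1 (0.89) and the adipocyte marker Lpl (0.75) were higher apart in the same library. Among rows with intervals apart the largest log2 fold changes were those of Sfrp2, a secreted antagonist of Wnt signalling, at 3.90, Fbln7 at 2.87, the growth factor gene Igf2 at 2.74, Col8a2 at 2.73 and the thrombospondin gene Thbs1 at 2.66. Thbs1 stood at 228 FPKM (197 to 260.2) in the control and 1454 FPKM (1151 to 1756) in the knockdown library. Serum response genes had a median of 0.25, with 16 of 46 higher apart and 2 lower apart, including Ptgs2 (1.67) and Egr2 (1.45).

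Cell cycle genes were lower in the knockdown library. Of 48 expressed members of the list, 43 were lower apart and 0 higher apart, and the median was -0.77 against a random range from -0.12 to 0.09. Of these, 4 members reached 2-fold, namely Cdc25c (-1.16), Ccne1 (-1.11), Uhrf1 (-1.02) and Ube2c (-1.01). The 5 expressed histone genes whose mRNA normally lacks a poly(A) tail, listed as a sign of RNA quality, also lay below the random range (median -0.69), with none apart. Hist1h4d was at 1.00 FPKM in the control and 0.239 FPKM in the knockdown library, and Hist1h2ae at 1.18 and 0.347 FPKM. Both entered only through the control and so had to be lower. Cyclin D1 was lower by more, with Ccnd1 at 192 FPKM (166 to 218) in the control and 61.96 FPKM (52.6 to 71.3) in the knockdown library. Leaving out rows with overlapping intervals, the lowest log2 fold changes in the knockdown library were those of the prolactin family row Prl2c3,Prl2c4 (-3.98), Sprr1a (-3.23), the neurofilament gene Nefl (-3.17), Prl2c2 (-2.76) and the granzyme gene Gzmd (-2.46). Reads of the near-identical Prl2c genes cannot be assigned to one copy with certainty. AF357399 was listed at 0 in the knockdown library and at 10.2 FPKM in the control, with overlapping intervals.

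FoxO, autophagy and atrophy genes were higher in the knockdown library by less than in the starved library. FoxO targets had a median of 0.40, with 11 of 31 members higher apart and 2 lower apart, the highest being Fbxo32 (1.65), Ypel3 (1.13) and Hbp1 (1.10). The autophagy core list had a median of 0.23, with 7 of 47 members higher apart and 1 lower apart. Its highest members were the mitophagy kinase gene Pink1 (1.19), Nrbf2 (0.98) and Atg13 (0.69). Ulk1 was at 12.1 FPKM (10.4 to 13.8) in the control and 16.6 FPKM (14.0 to 19.2) in the knockdown library, and Map1lc3b at 67.3 FPKM (51.8 to 74.5) and 98.1 FPKM (74.9 to 111). The intervals of Gabarapl1 and Sqstm1 overlapped, Sqstm1 being at 197 FPKM. In the atrophy list, with a median of 0.15, 5 of 30 members were higher apart and 1 lower apart, and Foxo1 was at 14.1 FPKM (11.1 to 16.6) against 6.08 FPKM (4.85 to 7.10) in the control. With the mean in place of the median, the autophagy and atrophy lists lay at the 97.2 and 96.1 percentiles, inside the central 95%, as did the atrophy list among unmatched random lists (97.1); the difference between the 2 comparisons was not tested.

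Several further lists had medians below the random range in the knockdown library. The list of hypoxia and glycolysis genes had a median of -0.43, with 11 of 34 members lower apart and 3 higher apart, including Egln3 (-1.17), Aldoa (-0.84) and the glucose transporter gene Slc2a1 (-0.74). Gapdh, a glycolytic enzyme gene often used as a reference, was at 992 FPKM (764 to 1100.0) in the control and 602 FPKM (459.8 to 689.8) in the knockdown library. Heat shock genes (median -0.36, 6 of 18 lower apart), proteasome genes (-0.33, 4 of 33), ribosome biogenesis genes (-0.27, 5 of 40) and NRF2 targets (-0.22, 3 of 22 lower apart and 2 higher apart) also lay below the random range, the last not clearly, since its mean stood at the 2.51 percentile. The amino acid response list, by contrast, had a median of -0.01 in the knockdown library, with 5 of 44 members higher apart and 7 lower apart, among the latter Atf3 (-1.34) and Phgdh (-0.89). Lysosome genes (median -0.000984), with 5 of 51 higher apart, and cholesterol synthesis genes (0.10), with 1 of 26 apart in each direction, were inside the random range.

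In total, 296 of 11357 expressed rows were at least 2-fold higher and 165 at least 2-fold lower in the knockdown library, of which 235 and 122 had intervals apart. With a pseudocount of 5 these numbers were 148 and 74, and with a pseudocount of 0.1 the lower rows numbered 269. Of 21 ranked lists, 6 lay above and 7 below the central 95% of random lists. The rows A330023F24Rik,Mir29b-2,Mir29c (log2 fold change 5.04) and Igf2bp1,Mir3063 (3.53), again with overlapping intervals, were among the highest rows ranked for naming, and Actr5,Mir3474 (-4.95) and Dgcr8,Mir1306 (-4.06) the lowest.

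**Figure D2:**
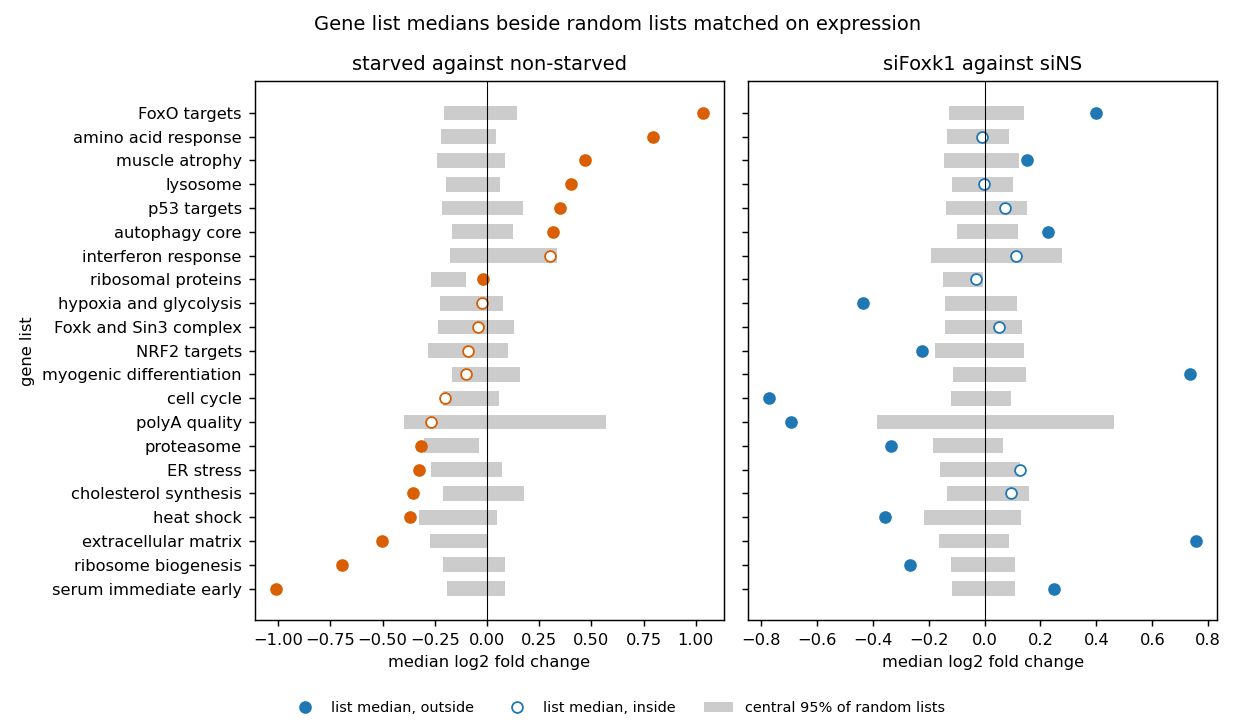
Median log2 fold change of each ranked gene list in the starved (left) and Foxk1 knockdown (right) library relative to the control. Grey bars span the central 95% of 10000 random lists of the same size matched on expression, filled points lie outside and open points inside; extracellular matrix genes stand at -0.50 on the left and 0.76 on the right, and FoxO targets at 1.03 and 0.40.

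The design text sets both treatments against the same non-starved control, which allows the genes higher or lower in both to be counted. On single-gene rows without short RNAs, 24 genes were at least 2-fold higher in both libraries, and all 24 had intervals apart in both. They included Dhrs3, a retinal reductase gene (log2 fold changes 2.05 and 2.29 in the starved and knockdown libraries), Fbxo32 (2.29 and 1.65), the chemokine gene Cxcl12 (1.48 and 1.44), Calcoco1 (1.32 and 1.37), the selenoprotein gene Sepp1 (1.31 and 1.58) and Maf (2.40 and 1.24). Without regard to size, 10 of 31 FoxO targets were higher apart in both, among them Gadd45a, Txnip, Irs2, Pdk4 and Sesn3, and so were 4 of 47 autophagy genes, namely Atg13, Map1lc3b, Ulk1 and Zfyve1. With 21 FoxO targets higher apart in the starved and 11 in the knockdown library, and 14 and 7 autophagy genes, part of this overlap would arise without a link. In each of these 2 lists 1 member was higher apart in the starved and lower apart in the knockdown library. Unchanged values were not simulated for single lists.

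At least 2-fold lower in both libraries were 21 such genes, 19 of them apart in both. Ccnd1 (log2 fold changes -1.99 and -1.62), the plasminogen activator inhibitor gene Serpinb2 (-2.05 and -1.57), the neurofilament gene Nefm (-1.47 and -2.25) and the natriuretic peptide gene Nppb (-1.42 and -1.40) were among them. Without regard to size, 8 of 48 cell cycle genes were lower apart in both, including Ccne1, Cdc6, E2f2, Mcm2 and Rrm2. As 43 of the 48 were lower apart in the knockdown library, most of the 9 lower apart in the starved library would be lower in both without any link. A further 3 were higher apart in the starved and lower apart in the knockdown library.

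Other genes differed in opposite directions. At least 2-fold lower in the starved and higher in the knockdown library were 13 single-gene rows, all apart in both comparisons, and none went the other way. Independent lists of the observed lengths would share 5.39 and 3.33. On all rows, including short RNAs and combined rows, 23 rows went the first way and 2 the other. The 13 included Thbs1, at 0.248 and 6.36 times the control in the starved and knockdown libraries, and by log2 fold change Acta2 (-1.59 and 1.98), Egr2 (-2.07 and 1.45), the imprinted RNA H19 (-1.19 and 1.63) and Myog (-1.11 and 1.61). By list and without regard to size, 12 of 46 serum response genes and 10 of 34 members of the extracellular matrix list were lower apart in the starved and higher apart in the knockdown library. The other way went 3 of 48 cell cycle genes. So did 1 member each of the autophagy core, FoxO target, amino acid response, heat shock and Foxk and Sin3 complex lists. In the serum response list 31 genes were lower apart in the starved and 16 higher apart in the knockdown library. In the extracellular matrix list these counts were 18 and 23. Opposite counts near 12 and 10 would therefore arise in these 2 lists without any link.

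Both comparisons share the 1 control library, whose noise moves them together. Simulated unchanged libraries with that shared control gave an average of 8.10 genes higher in both (at most 17 in 1000 simulations) and 2.21 lower in both (at most 8), while independent lists of the observed lengths would share 5.87 and 3.06. On all rows, including short RNAs and combined rows, 34 rows were higher in both, inside the simulated range (average 25.9, at most 50), and 51 were lower in both (average 8.92, at most 19). The control cannot be split, so part of any excess may come from it. The simulated libraries hold few 2-fold rows, so their counts leave out the coincidental overlap that the independent lists give. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.344 on all rows and 0.185 on the single-gene rows (Spearman 0.220 and 0.218). The simulated unchanged libraries gave a higher r, 0.484 on average (at most 0.682) on all rows and 0.469 (at most 0.538) on single-gene rows. The simulated libraries hold noise only, so the shared control gives them a high r, and differences of 1 library alone lower the observed r. The observed r therefore cannot show whether there is sharing beyond noise of the control. The covariance on single-gene rows was 0.0400, above the simulated average of 0.0242 and maximum of 0.0303, and on all rows 0.115, above 0.0424 and 0.0903.

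**Figure D3:**
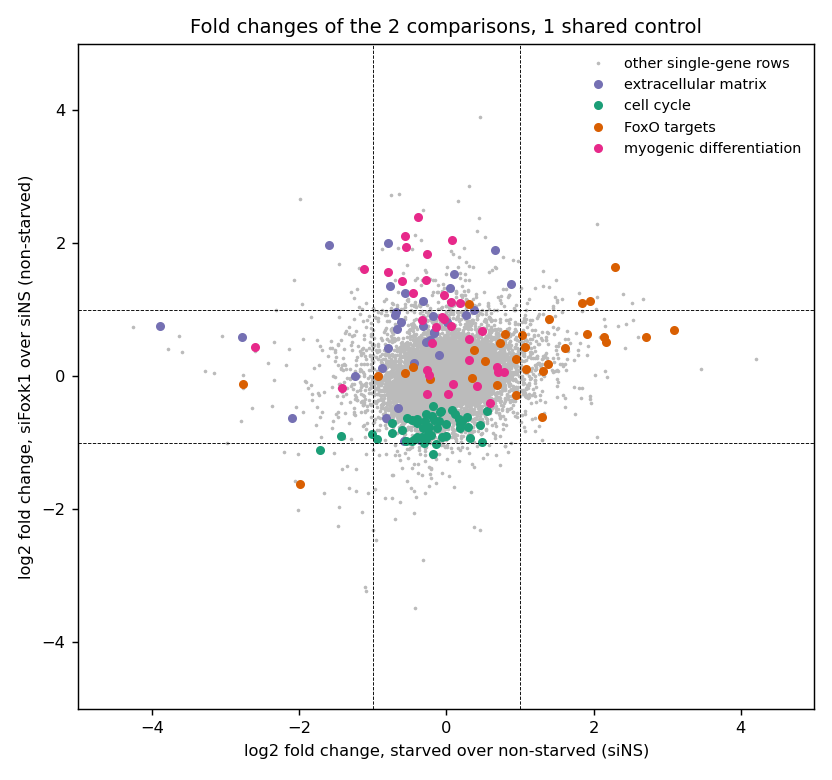
Log2 fold change in the starved library (horizontal) against that in the Foxk1 knockdown library (vertical), both relative to the same control, for single-gene rows without short RNAs. Colours mark 4 gene lists and dashed lines a 2-fold change; cell cycle genes lie low on the vertical axis (median -0.77), and myogenic genes lie high (median 0.74).

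The ChIP-seq lists held 8857 Foxk1 regions and 16773 distinct Sin3A regions on mouse build mm9, with no score for any region. Foxk1 regions were 584 bases wide at the median (quartiles 470 and 729) and covered 5.54 Mb, and Sin3A regions were 690 bases wide (505 and 1121) and covered 14.97 Mb. Of the Foxk1 regions, 2814 (31.8%, exact binomial interval 30.8 to 32.8) shared at least 1 base with a Sin3A region. Of the Sin3A regions, 2767 (16.5%, 15.9 to 17.1) shared at least 1 base with a Foxk1 region. Random placement of the regions within their chromosomes gave an average overlap of 1.21% of Foxk1 and 0.631% of Sin3A regions, and at most 1.52% and 0.787% in 100 placements. Random placement takes no account of open chromatin or promoters, so it gives a floor. The intervals cover counting error only.

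Shared regions were wider at the median in both lists. Foxk1 regions that overlapped Sin3A had a median width of 633.5 bases against 567 for the others, and Sin3A regions that overlapped Foxk1 1127 against 636 bases. When each list was divided by width into 4 groups of nearly equal number, the shares of Sin3A regions that overlapped a Foxk1 region were 5.22%, 6.37%, 20.96% and 33.4% from the narrowest to the widest group. For Foxk1 regions the shares were 27.4%, 25.7%, 29.1% and 44.9%, so that only the widest group stood apart. Wider regions have more bases to share, so width and overlap are not independent. The widest Foxk1 region (chromosome 11, bases 74643033 to 74645932) overlapped a Sin3A region, and the widest Sin3A region (chromosome 6, bases 52172759 to 52180333) overlapped no Foxk1 region; both were chosen after their widths were seen. No gene annotation of this build was used here, so regions are not assigned to genes.

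Region density differed between chromosomes. In both lists it was highest on chromosome 15, with 8.85 Foxk1 and 15.2 Sin3A regions per Mb, followed by chromosome 11 with 6.25 and 11.4, where the median autosome had 3.07 and 6.14. On chromosome 15 only 20.0% of 915 Foxk1 regions overlapped a Sin3A region (17.5 to 22.7), the lowest share of any autosome, and on chromosome 7 47.0% (40.8 to 53.2), the highest. The X chromosome carried 0.571 Foxk1 and 2.07 Sin3A regions per Mb, or 27.5 Foxk1 regions per 100 Sin3A regions, where the median autosome had 54.4. Each list also held 11 regions on the mitochondrial genome.

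**Figure D4:**
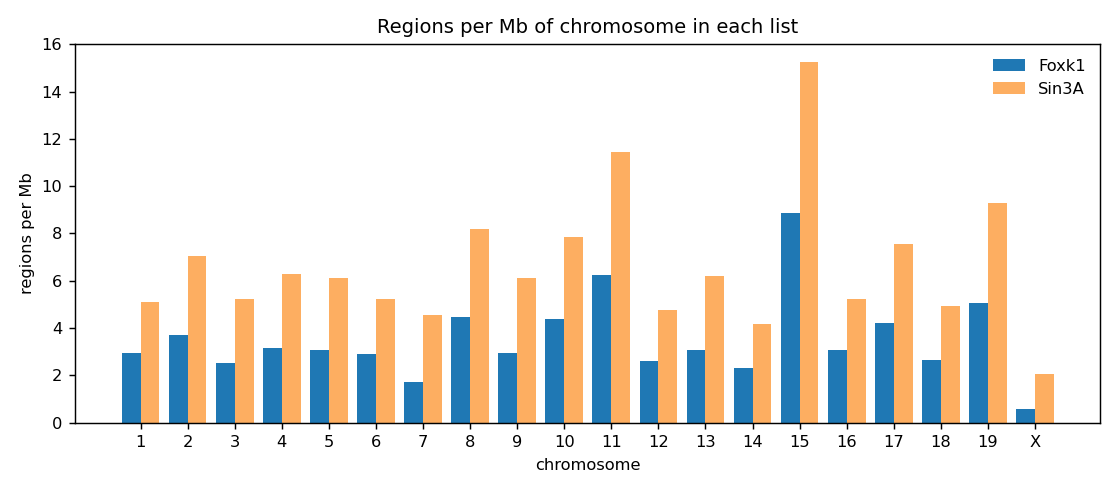
Regions per Mb of each chromosome in the Foxk1 (blue) and Sin3A (orange) lists, with chromosome lengths taken as the highest region end in either list. Bars are counts divided by length, start at 0 and have no replicate error; chromosome 15 stands highest in both lists, at 8.85 and 15.2 regions per Mb.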

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

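The settings without short RNA, combined and repeated rows, with intervals apart, and without chromosome 15 were chosen after seeing the data. Counts of 2-fold rows depended on the pseudocount, on the fold itself and on the kinds of row kept. With a pseudocount of 0.1, 562 rows were higher in the starved library (356 in the report), 269 lower in the knockdown library (165) and 60 higher in both (34). With 5, which shrinks the fold of low rows, 154 were higher and 179 lower (342) in the starved library, 148 higher (296) and 74 lower in the knockdown library, and 16 higher in both. At 1.5-fold, by construction, the 6 counts were 1175 and 1085 for starvation, 879 and 706 for knockdown, and 184 and 151 in both; at 3-fold they were 90 and 115, 91 and 64, and 12 and 28. Rows lower in both, 51 in the report, numbered 21 without short RNA, combined and repeated rows and 19 with intervals apart. A floor of 5 FPKM and both rescalings left the 6 counts within 1.5 times, and dropping the filter left them identical, since with a pseudocount of 1 a 2-fold change needs 1 FPKM.

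The correlation of the fold changes, 0.344, was 0.413 and 0.313 with pseudocounts of 0.1 and 5, 0.373 at 5 FPKM and 0.294 without a filter. It was 0.220 as Spearman's coefficient and 0.185 without short RNA, combined and repeated rows. The cause of these differences was not tested. Simulated unchanged libraries with the shared control, run with a pseudocount of 1 only, gave a Pearson average of 0.484 on all rows and 0.469 on single-gene rows. The number of lists outside the central 95% ranged from 11 to 16 for starvation and from 10 to 14 for knockdown. The position of 2 lists turned around in the starvation comparison: ER stress genes lay at the 63.1 percentile by their mean, and ribosomal proteins at the 43.9 percentile among random lists not matched on expression. Of all single-list values under the alternatives, 235 kept their place, 6 moved inside the central 95% and 5 outside it. In both cases of turning around, the alternative's construction shows why: the mean follows the few high members, and abundant genes as a class were lower.

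The share of Foxk1 regions overlapping Sin3A (31.8%) was 30.5% when 50% of the smaller region had to be shared, 34.9% within 1000 bases and 33.1% without chromosome 15. The share of Sin3A regions overlapping Foxk1 (16.5%) was 15.8% and 19.3% under the first 2 settings. The higher-scoring part of each list, and every alternative on transcription start sites or bound genes, was not run, for want of a score and of an annotation of mm9. Unknown read depth limits all low rows.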

Other observations

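In this part, the tests of the shared covariance, of the short RNA rows, and of local clusters and antibody specificity on chromosome 15 were chosen only after the result was seen. Among the Foxk and Sin3 complex genes, 5 of 29 were higher apart in both the starved and the knockdown library: Kdm5a, Kdm5b, Mnt, Mxd1 and Mxd4. Mnt and the Mxd genes encode partners of MAX that oppose MYC, and the Kdm5 genes encode histone demethylases. The list medians were -0.04 in the starved library, with 7 members higher apart and 4 lower apart, and 0.05 in the knockdown library, with 6 and 1, both inside the random range. Mnt had a log2 fold change of 1.19 in the starved library and Mxd4 of 1.15 in the knockdown library.

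Interferon response genes, which double-stranded RNA can induce, were not outside the random range in either comparison (medians 0.30 and 0.11), with 6 of 18 members higher apart and 1 lower apart in the starved library and 2 of 13 higher apart in the knockdown library. All 3 libraries were given siRNA, so a response to siRNA in general could not show in either comparison. The starved library's most changed members, Cxcl10, Irf7, Ifit1 and Tap1, were under 1 FPKM in the control. They entered only through the starved library and so had to be higher there. In the starved library the interferon list lay at the 95.4 percentile, but outside the central 95% at 99.0 with a pseudocount of 5 and at 99.4 among random lists not matched on expression, and further inside at 91.7 with a pseudocount of 0.1 and at 63.4 among rows of 5 FPKM or more. Hypoxia and glycolysis genes (median -0.03, 6 of 35 apart in each direction) and NRF2 targets (-0.09, 4 of 23 higher apart and 1 lower apart) were inside it in the starved library, although Ndrg1 (2.52) and Slc7a11 (1.85) were high. Slc7a11 also stands in the amino acid response list. It was at 0.346 FPKM in the control and 3.85 FPKM in the starved library, so it entered only through the latter and had to be higher. In the knockdown library p53 targets (0.07, 4 of 26 higher apart and 3 lower apart), ER stress genes (0.13, 3 of 26 and 1) and ribosomal proteins (-0.03) were inside the random range as well, although ER stress genes lay outside at the 98.5 percentile with a pseudocount of 5. Of the histone genes whose mRNA normally lacks a poly(A) tail, only 5 were expressed. In the starved library their median of -0.27 was inside the random range and Hist1h2bc was higher apart (1.06), and in the knockdown library the median of -0.69 lay below it with none apart. Hist1h4d and Hist1h2ae entered both comparisons only through the control and so had to be lower. Markers of other cell types were few: 3 adipocyte, 4 bone and cartilage, 2 immune and 0 endothelial genes were expressed in the starved comparison. There Plin4 was higher apart and Dmp1, Sox9 and Spp1 lower apart, and in the knockdown library Lpl and Dmp1 were higher apart. Plin4 was under 1 FPKM in the control, entered only through the starved library and so had to be higher there. The bone-associated gene Spp1 was abundant, at 2884 FPKM in the control, 1540.0 FPKM in the starved and 2712 FPKM in the knockdown library.

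Set against simulated noise of the shared control, the fold changes of the 2 comparisons shared more by covariance. It was 0.0400 against a maximum of 0.0303 on single-gene rows and 0.115 against 0.0903 on all rows. On single-gene rows, 24 genes against at most 17 were higher and 21 against at most 8 lower in both. On all rows, 51 against at most 19 were lower in both, while the 34 rows higher in both were inside the simulated range (at most 50). The simulated libraries held far fewer 2-fold rows, on average 15.2 single-gene rows higher in the starved library, where 318 were observed. Their counts leave out coincidental overlap of rows that differ, so the counts cannot decide on sharing. Pearson's r was below the simulated average, at 0.185 against 0.469 on single-gene rows and 0.344 against 0.484 on all rows. Differences of 1 library alone lower r, so r cannot decide on sharing either. The simulated values assume noise as wide as the authors' intervals, which no replicate checks, so noise of the control stays open as a source of part of the sharing. A control library that departed from its group for these genes would put the starved and knockdown libraries at the same level. Their intervals overlapped for 66.7% of the 24 genes higher in both and 61.9% of the 21 lower in both, between the bounds of 50% and 80% set before the result was seen. For these genes a departed control and a response common to starvation and Foxk1 depletion cannot be told apart, since there is 1 control library.

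Rows of microRNAs, snoRNAs and other short RNAs supplied many 2-fold values, 91 in the starved and 86 in the knockdown comparison. Of these, 98.3% had overlapping intervals, against 2.82% in rows that were neither short RNAs nor combined; in combined rows the share was 60% in the starved and 62.5% in the knockdown comparison. This is consistent with unstable FPKM of very short transcripts. No biological explanation was tested.

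Chromosome 15 held more regions in both lists than its length would give. A few local clusters would leave its typical stretch ordinary, but its median 5 Mb bin held 3.39 times the regions of the median bin of the other autosomes in the Foxk1 list. Binding specific to one antibody would give different excesses. Relative to the median autosome the Foxk1 excess was 1.16 times that of Sin3A, below the 1.5 set for it. The interval put around it (1.07 to 1.27) leaves out 1 and crosses the 1.2 set against it. Its width came from counts pooled over the other autosomes, so it is not the counting error of a ratio to the median autosome. Chromosome 15 held 58.0 Foxk1 regions per 100 Sin3A regions, inside the range of the autosomes (38.2 to 58.6). Binding specific to one antibody stays open. Extra copies of chromosome 15 in this cell line may raise the regions called in any ChIP: 85% of its bins (17 of 20) exceeded the median bin of the other autosomes in the Foxk1 list, for which the bounds of 75% and 90% were set, and 95% (19 of 20) did in the Sin3A list. The first lies between the bounds and the second above them, so this stays open, as input reads were not analysed here, and no biological explanation was tested.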
